A study of Arabidopsis thaliana with 18 samples.

How the data were processed

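RNA from an Arabidopsis thaliana cell suspension was hybridised to 18 Affymetrix arrays, 3 biological replicates at each of 6 stages. Per the labels' protocols, the logarithmic phase of the cultures was prolonged by dilution or by a change of medium, cell pellets were frozen, total RNA was extracted with a plant RNA kit and biotin-labelled cRNA was made from it. The stages were grouped by the labels' localization of glutathione (GSH): GSHn1, GSHn2 and GSHn3 are stages with GSH in the nucleus, and GSHc1, GSHc2 and GSHc3 are stages with GSH in the cytoplasm. The labels also give the time after inoculation and whether the culture was a control or had its medium changed.

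The authors deposited normalized intensity values, 1 per probe set and array. Per the submitters' processing notes the values were made with RMA; its version and any later step are not given in the sources used here. The values are linear: they ran from 0.78 to 2524.1, array medians lay between 2.18 and 2.35, and 46.9% to 48.3% of the probe sets of an array were under an intensity of 2. Many values therefore lie close together at the lower end. The relation of this scale to the usual RMA scale is unknown, and no detection call was used here. The design fixed before the data were examined took the deposited values to be on a log2 scale already; because they are linear, log2 of each value was taken with no pseudocount. Folds against a dim group may be understated if the scale is compressed at its lower end, which was not tested. The number of arrays limits the precision.

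The table held 22746 probe sets and no control probe sets, and all were tested without a filter. The annotation used names 1 gene for 13513 probe sets and several genes for 503, and the other 8730 are unnamed here. Of 13356 distinct genes named, 13286 were matched to RefSeq symbols (assembly TAIR10.1), and the array's symbol or locus was kept otherwise. Most genes carry a locus identifier in place of a symbol.

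Tests of expression used limma 3.58.1 in R 4.3.3: lmFit on the 6 stage means over all 18 arrays, then eBayes with default settings, and Benjamini-Hochberg adjustment over all probe sets with a threshold of 0.05. Differences are on the log2 scale, nuclear minus cytoplasmic or later minus earlier, with their standard errors (SE). The moderated F test was used among the 3 stages of each localization. Chromosomes were compared by Fisher's exact test on named probe sets called at 2-fold or more, adjusted over all 80 tests and added after the values were seen; it treats genes as independent, which they are not. Tables were handled with pandas 2.3.3 in Python 3.11.15 and data.table (version 1.17.8). The residual spread is that of replicates within a stage, so a p-value speaks of these 6 stages and not of stages in general. The labels call the replicates biological and do not say whether they were separate cultures grown apart.

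Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene (that of the highest mean), adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and the counts of members, adjusted over all probe sets and over the list alone. There were 24 preset lists with 503 members, of which 92 were measured by a probe set of 1 gene; lists with at least 3 such genes were tested, a limit set after the annotation was read. Because so few were named, 22 further lists were added from the annotation table after it was read and before any comparison was computed, and were adjusted apart from the preset lists. Of 98 tests of preset lists 29 were called and 4 of these held with an estimated correlation; of 154 tests of added lists 55 were called and 19 held. The list of core histones with shared probe sets keeps probe sets of several genes.

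Named genes followed a rule fixed beforehand: in each comparison the 5 probe sets with the largest difference in each direction among those past the threshold, of 1 gene, whose groups did not overlap. For several stages this means that every nuclear stage mean lay beyond every cytoplasmic one. In a comparison of 2 stages, all 3 arrays of a stage lay beyond all 3 of the other. The condition could not be applied to the difference between 2 effects, which has no pair of groups. Called lists give up to 3 members in their direction and 2 in the other, and lists not called at most 2 members. GSH1, GSH2, BAG6, PARP1, PARP2, CYCD3;1, CYCB1;1, PCNA1, APX1 and CAT2 were to be named in any case and are not analysed here, since no probe set is named for them alone in the annotation used.

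The computation was tested on simulated arrays with 200 changed probe sets among 22746. Each probe set had its measured mean over all arrays and its within-stage spread. Apart from the added changes the simulated stages did not differ. The recovery and false calls therefore do not show what differences between stages of a localization do to the calls. The changed probe sets were drawn from those with a mean above log2 2, so the recovery does not speak of dimmer ones. For the comparison of all nuclear with all cytoplasmic stages, 95% of 1.5-fold changes and 99.5% of 2-fold changes were recovered, with 10 and 7 false calls, and 19 beside 4-fold changes. For the comparison of stages at 78 h, 51.5% of 1.5-fold and 95% of 2-fold changes were recovered, with 8 and 4 false calls, and 15 beside 4-fold changes. In a simulation of camera on 21 lists of 20 genes, the 1 shifted list was called and so was 1 of 20 unshifted lists, at an adjusted p of 0.0164 in limma's camera. The simulated probe sets varied independently, so this run cannot show what correlation between genes does to the calls.

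Alternatives were the replicate number as a block, eBayes with trend and robust settings, median centring, quantile normalization, array weights, omission of probe sets of shared sequence, a filter at a stage mean above log2 6, omission of each array or stage, only the arrays compared, calls of at least 2-fold, and the stage as the unit. A filter at log2 2 was chosen after the scale of the values had been seen.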

Results

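Transcript levels were measured in an Arabidopsis cell suspension, a culture of dividing cells in liquid medium, at stages in which glutathione (GSH, the main low-molecular-weight thiol of the cell) lay in the nucleus or in the cytoplasm. The question set by the design was how gene expression differs between those states. Nuclear stages were GSHn1 at 6 h, GSHn3 at 78 h and GSHn2 at 198 h after inoculation, and cytoplasmic stages were GSHc1 at 78 h, GSHc2 at 102 h and GSHc3 at 174 h. Cultures of GSHn3 and GSHc3 had their medium changed, and the other 4 stages were control cultures. Each stage had 3 biological replicates, so 9 arrays stood on each side. Within a stage, pairs of arrays correlated at 0.99 to 0.996 across probe sets on the log2 scale. Time, medium and localization go together in this design, and no pair of stages differs in localization alone.

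The first principal component held 44% of the variance, and along it stages lay in the order of culture age, from GSHn1 to GSHn2, with GSHc3 next to GSHn2. The second held 28.2% and parted the control stages by localization, GSHn1 and GSHn2 from GSHc1 and GSHc2. The media-change stages lay between these, nuclear GSHn3 nearer to the cytoplasmic control stages than GSHc3. Stage means of GSHn2 and GSHc3, with GSH in different places, correlated at 0.981, whereas those of the nuclear stages GSHn1 and GSHn2 correlated at 0.914. GSHn3 and GSHc1, both at 78 h, correlated at 0.983. These correlations run across probe sets, which are not independent replicates.

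**Figure D1:**
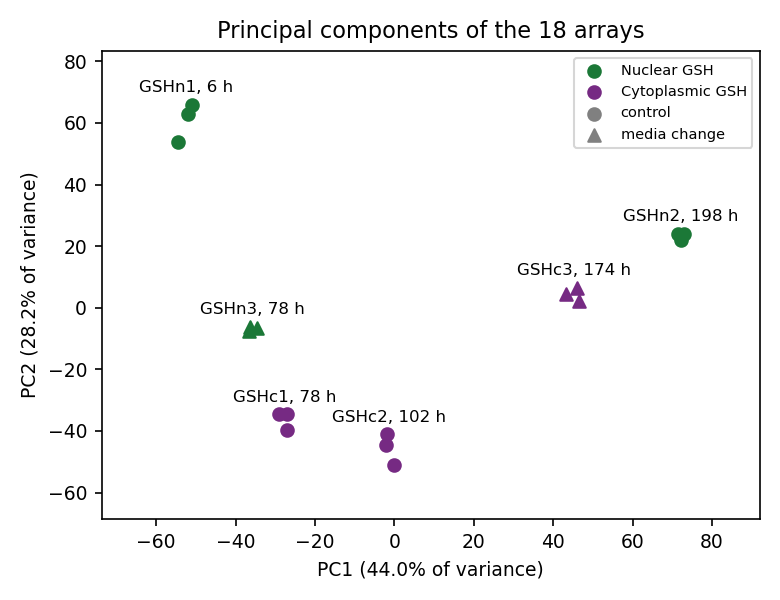
Principal components of the log2 intensities of the 18 arrays, with PC1 (44% of variance) on the horizontal and PC2 (28.2%) on the vertical axis. Each point is 1 array, coloured by GSH localization and shaped by medium; the 198 h nuclear and 174 h cytoplasmic stages lie close together on the right.

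Between all nuclear and all cytoplasmic stages, ribosome biogenesis genes were higher and small heat-shock protein genes lower on average, but not at every stage. The list median of ribosome biogenesis was 5.11 at GSHn1 and 4.1 at GSHn3, and 2.27 at nuclear GSHn2, below GSHc1, GSHc2 and GSHc3 (3.53, 2.72 and 2.76). That of small heat-shock proteins was 0.97 at cytoplasmic GSHc3, below GSHn1 (3.43) and GSHn3 (2.85). Of 17 measured ribosome biogenesis genes, which make and assemble ribosomal subunits, 16 rose and 0 fell. This list was added from the annotation. The preset list of ribosome biogenesis and ribosomal proteins, with 3 genes measured, was not called. AT3G12860 was higher by 1.16 ± 0.09 (SE) on the log2 scale, AT5G66540 by 1.01 ± 0.09 and AT4G04940 by 0.98 ± 0.09. The added list was called by camera at an adjusted p of 1.84e-13, and the call held at an adjusted p = 0.00111 with an estimated correlation. Of 8 small heat-shock protein genes, which encode chaperones, 6 fell, all by at least 2-fold. AT2G29500 fell by 3.01 ± 0.17, AT1G53540 by 2.72 ± 0.15 and AT5G37670 by 2.59 ± 0.24. That list had an adjusted p of 6.39e-08, and an adjusted p = 0.0999 with an estimated correlation. Of 94 cytosolic ribosomal protein genes 34 rose and 4 fell (adjusted p = 1.37e-05, and adjusted p = 0.253 with an estimated correlation). Their median was 8.33 at GSHn1, 8.4 at GSHn3 and 7.05 at GSHn2, the lowest of all stages, against 8.25, 7.72 and 7.45 at GSHc1, GSHc2 and GSHc3.

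Histone genes were also higher on average in the nuclear stages, although cytoplasmic GSHc3 had a list median of 6.67 against 6.68, 6.28 and 6.23 at GSHn1, GSHn2 and GSHn3. All 4 measured core histone genes of the preset list rose, with HTB1, an H2B histone, higher by 0.71 ± 0.07 and HTB11 by 0.63 ± 0.06. The count was 4 adjusted over the list alone too. Camera gave an adjusted p of 0.00141, and an adjusted p = 0.0833 with an estimated correlation. With the shared probe sets added, 12 of 14 histone probe sets rose (adjusted p = 7.29e-09, and adjusted p = 0.0999 with an estimated correlation). All 3 measured photosynthesis genes fell, 3 of them adjusted over the list alone: RCA, which encodes Rubisco activase, by 1.68 ± 0.09, PRK, phosphoribulokinase, by 1.14 ± 0.11 and LHCB4.1, a light-harvesting protein, by 1.09 ± 0.07. The list had an adjusted p of 8.02e-05, and an adjusted p = 0.0833 with an estimated correlation. The list median was lowest at the 6 h stage, 3.66 ± 0.18 (SD, n = 3) on the log2 scale against 5.89 ± 0.04 at 198 h, also nuclear.

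Of genes directly tied to GSH, few were measured by a named probe set. GR1, a glutathione reductase, differed by -0.08 ± 0.06 between nuclear and cytoplasmic stages (adjusted p = 0.379), and GR, the plastid and mitochondrial glutathione reductase at AT3G54660, by -0.15 ± 0.09 (adjusted p = 0.238). Of 14 glutathione transferases 2 fell and 0 rose, with 2 adjusted over the list alone. GSTL3 fell by 0.84 ± 0.08 and the list was not called (camera adjusted p = 0.135). Its median log2 level lay between 0.26 (GSHn3) and 0.4 (GSHc3), near the lower end of the scale. Many members were therefore dim, and the lack of a call says little about them. Among 12 glutaredoxins, thioredoxins and peroxiredoxins 1 rose and 4 fell, with the same counts adjusted over the list alone. PRXIIF, the mitochondrial peroxiredoxin, fell by 0.39 ± 0.06, and that list was not called either (adjusted p = 0.199). Of 3 reference genes 0 passed the threshold in limma between all nuclear and all cytoplasmic stages, and 0 adjusted over the list alone. They were not level across stages: their median was 4.24 at GSHn1 and 4.2 at GSHc3, against 4.61 (GSHc1) to 4.72 (GSHc2) at the other stages.

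The largest differences with every nuclear stage mean beyond every cytoplasmic one were AT2G39210, higher by 2.95 ± 0.11 (7.71-fold), and AT2G38870, AT2G39650, AT3G15640 and AT2G39400, higher by 1.95 ± 0.15, 1.58 ± 0.09, 1.58 ± 0.1 and 1.53 ± 0.09. Lower were AT1G06620 by -3.23 ± 0.12 (9.41-fold), AT4G33660 by -2.51 ± 0.11, AT3G61870 by -2.01 ± 0.07, AT3G48420 by -1.92 ± 0.11 and HPR, the photorespiratory hydroxypyruvate reductase, by -1.9 ± 0.08. Their adjusted p-values in limma lay at or below 3.93e-09. AT1G06620 shows how the stages differ: its level was 31.1 at GSHc1 and 44.1 at GSHc2 but 1.54 at GSHc3, and 1.42, 1.31 and 1.36 at GSHn1, GSHn2 and GSHn3. GSHc3 and the nuclear stages were all under an intensity of 2, so their order and the exact fold are uncertain. Most of the rises named here lie on chromosome 2, which led to a test of chromosomes after the values were seen. Of 83 named probe sets higher by at least 2-fold 20 (24.1%) lay on chromosome 2, against 16.5% of 13367 named probe sets (Fisher's exact test, adjusted p = 0.776). Over all chromosomes, comparisons and directions 0 of 80 such tests passed; regions within a chromosome were not tested.

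In limma 7549 of 22746 probe sets passed the threshold, 3990 higher and 3559 lower, and 625 of them differed by at least 2-fold, 214 higher and 411 lower. Every nuclear stage mean lay beyond every cytoplasmic one in 8.7% of probe sets, against 10% by chance for 3 against 3. With the 6 stage means as units no probe set passed (0 at the adjusted threshold). At an unadjusted p under 0.05 in limma stood 787, or 3.5%, a share below that expected by chance. With the stage as a random block 7 passed, and 10.6% had an unadjusted p under 0.05. The moderated F test called 11044 probe sets among the nuclear stages alone and 8348 among the cytoplasmic stages alone.

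**Figure D2:**
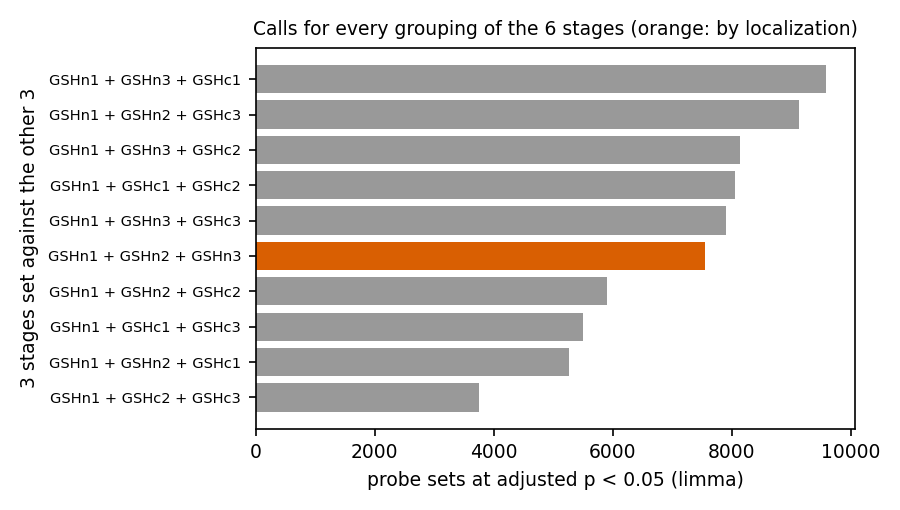
Number of probe sets past the limma threshold (horizontal axis) for each of the 10 ways to set 3 stages against the other 3 (vertical axis, naming the side that holds GSHn1). The localization grouping, in orange, called 7549, and the grouping of GSHn1, GSHn3 and GSHc1 against the other stages called 9585.

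Within the control cultures the nuclear stages, 6 h and 198 h, were set against the cytoplasmic stages, 78 h and 102 h. Small heat-shock protein genes fell by large folds: 6 of 8 fell by at least 2-fold, with AT2G29500 lower by -6.26 ± 0.21 (76.5-fold), AT1G53540 by -5.78 ± 0.18 (54.9-fold) and AT5G37670 by -4.48 ± 0.3. AT5G48570, which encodes a heat-inducible immunophilin, was lower by -5.1 ± 0.11, at 55.2 and 3.8 in GSHn1 and GSHn2 against 427 and 581 in GSHc1 and GSHc2. The list had an adjusted p of 1.02e-07, and an adjusted p = 0.063 with an estimated correlation. All 4 core histone genes rose, 4 adjusted over the list alone, and HTB1 was higher by 1.23 ± 0.08, HTB11 by 1.0 ± 0.07 and HTB2 by 0.92 ± 0.08. Camera gave an adjusted p of 0.000312, and an adjusted p = 0.0744 with an estimated correlation.

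Of 20 genes of mitosis and cytokinesis 12 fell and 1 rose, with AUR3, an Aurora kinase, lower by -1.15 ± 0.12, BUBR1, a spindle checkpoint protein, by -1.06 ± 0.1 and AT3G20150 by -1.01 ± 0.13. HTR12, the centromeric histone H3, rose by 0.7 ± 0.09. The list had an adjusted p of 0.000173, and an adjusted p = 0.105 with an estimated correlation. Its median level was 1.98 at GSHn1 and 2.48 at GSHn2, against 2.77 at GSHc1 and 2.42 at GSHc2. Among 14 expansins and xyloglucan endotransglucosylases, which loosen and remodel the cell wall, 8 rose and 2 fell, and the same numbers held adjusted over the list alone. XTH18 was higher by 2.12 ± 0.14, XTH19 by 1.79 ± 0.15 and EXLA2 by 1.62 ± 0.09, whereas XTH20 and EXPA15 were lower by -0.98 ± 0.14 and -0.68 ± 0.19. Camera gave an adjusted p of 0.00517, and an adjusted p = 0.0744 with an estimated correlation. The median level of this list was 4.54 at GSHn1 and 1.4 at GSHn2, against 3.01 at GSHc1 and 3.84 at GSHc2. Class III peroxidases rose in 17 of 55 cases and fell in 2 (camera adjusted p = 0.000551, and adjusted p = 0.105 with an estimated correlation). AT5G64120, AT5G39580 and AT2G37130 were higher by 3.2 ± 0.14, 3.16 ± 0.14 and 3.04 ± 0.14. The rise of AT2G37130 came from 198 h, and GSHn1 lay close to GSHc1. Many members were dim: the list median was 0.37 at GSHn1 and GSHn2, against 0.35 at GSHc1 and 0.34 at GSHc2.

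Beta-glucosidases rose in 8 of 20 cases and fell in 0, led by BGLU28, a gene known to be induced by sulfur shortage, which was higher by 4.02 ± 0.18 (16.2-fold), and by BGLU46 at 2.55 ± 0.22 and BGLU45 at 1.83 ± 0.15. The list had a camera adjusted p of 0.0035, and an adjusted p = 0.063 with an estimated correlation. Many of its members were dim: its median was 0.47 at GSHn1 and 0.53 at GSHn2, against 0.3 at GSHc1 and 0.39 at GSHc2. Mitochondrion-encoded genes rose in 11 of 15 cases, with nad9 higher by 1.39 ± 0.12 and cox1 by 1.3 ± 0.15 (adjusted p = 0.000469, and adjusted p = 0.063 with an estimated correlation). The median of these genes was 2.34 at GSHn2, but 1.1 at GSHn1 against 0.89 at GSHc1 and 1.08 at GSHc2. Of 94 cytosolic ribosomal protein genes 58 fell and 3 rose, none by 2-fold, with AT1G15930 lower by -0.89 ± 0.06 (adjusted p = 2.66e-09, and adjusted p = 0.0904 with an estimated correlation). Their median was low at GSHn2 only, 7.05, and at GSHn1 (8.33) it lay above GSHc1 (8.25) and GSHc2 (7.72). The other genes of largest difference were AT2G39210, AT2G37840, AT2G41730 and AT2G47550, higher by 4.4 ± 0.14, 3.44 ± 0.16, 3.28 ± 0.16 and 3.27 ± 0.15, and AT4G39675 and AT2G17850, lower by -5.71 ± 0.19 and -5.11 ± 0.14. The probe set of AT2G41730 is of a kind marked for shared sequence, so its level is uncertain.

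This control comparison called 8729 probe sets, 4396 higher and 4333 lower, of which 779 and 801 differed by at least 2-fold. Stage means did not overlap in 39.3% of probe sets, against 33.3% by chance for 2 stages against 2. With the stage as a random block 1805 probe sets passed. That fit used a shared correlation of 0.5 for all probe sets and still counted single arrays. It is therefore not a test of 2 stages against 2.

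In the media-change cultures the nuclear stage GSHn3 at 78 h was set against the cytoplasmic stage GSHc3 at 174 h. Ribosomal genes were higher in GSHn3: 93 of 94 cytosolic ribosomal protein genes rose, 32 of them by at least 2-fold, with AT4G30800 higher by 2.53 ± 0.14, AT5G59240 by 2.28 ± 0.12 and AT2G37600 by 1.58 ± 0.14. All 17 ribosome biogenesis genes rose, 13 by at least 2-fold; AT3G12860 was higher by 2.4 ± 0.16 and NRPA1, the largest subunit of RNA polymerase I, by 1.74 ± 0.14. Both calls (adjusted p = 2.04e-49 and 2.62e-16) held at adjusted p = 0.000589 and 0.000483 with an estimated correlation. The control comparison had the opposite direction for ribosomal proteins on average, though not at GSHn1. Core histones fell in 3 of 4 cases, 3 adjusted over the list alone, and were not called (adjusted p = 0.0817). With the shared probe sets added 13 of 14 fell (adjusted p = 4.29e-07, and adjusted p = 0.15 with an estimated correlation). Mitochondrion-encoded genes fell in 9 of 15 cases, with ccb452 lower by -2.29 ± 0.19 and nad9 by -2.16 ± 0.17 (adjusted p = 5.45e-05, which held at adjusted p = 0.0238 with an estimated correlation).

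Small heat-shock protein genes rose in 5 of 8 cases in this pair, with AT2G29500 higher by 3.49 ± 0.29, AT1G53540 by 3.38 ± 0.26 and AT1G54050 by 3.1 ± 0.2, while AT4G21870 fell by 0.38 ± 0.14. Camera gave an adjusted p of 0.00125, and an adjusted p = 0.178 with an estimated correlation. Genes of mitosis and cytokinesis rose in 12 of 20 cases and fell in 1, AT3G20150 by 1.55 ± 0.18 and BUB3.2, a spindle checkpoint gene, by 1.09 ± 0.13 (adjusted p = 0.000169, and adjusted p = 0.17 with an estimated correlation). Of 7 sugar starvation, senescence and autophagy genes 3 fell and 0 rose, 3 adjusted over the list alone: ATG8F and ATG8E, which encode ubiquitin-like proteins of the autophagosome, by 1.64 ± 0.12 and 1.48 ± 0.19, and PPDK by 0.73 ± 0.14 (adjusted p = 0.00927, and adjusted p = 0.12 with an estimated correlation). Cell wall genes went both ways: 6 of 14 expansins and xyloglucan endotransglucosylases fell, XTH19 by 4.51 ± 0.21, EXLA2 by 3.02 ± 0.12 and EXLA3 by 2.07 ± 0.13, and 2 rose, EXPA15 by 4.15 ± 0.28 and XTH20 by 2.35 ± 0.2 (adjusted p = 0.0239, and adjusted p = 0.157 with an estimated correlation).

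The largest rises beside EXPA15 were those of AT2G17850, AT3G15357, AT1G72230 and AT5G10040, at 4.45 ± 0.2, 4.36 ± 0.16, 4.24 ± 0.21 and 4.07 ± 0.3. Falls were largest for AT5G20790 at -5.86 ± 0.29 (58.1-fold), AT1G23140 at -4.97 ± 0.2, AT1G12010, an ACC oxidase of ethylene synthesis, at -4.95 ± 0.21, AT2G30930 at -4.83 ± 0.14 and AT3G03150 at -4.7 ± 0.2. In limma 7100 probe sets passed, 3799 higher and 3301 lower, and 798 and 999 differed by at least 2-fold. All arrays of a stage lay beyond all of the other in 41.5% of probe sets, against 10% by chance. Time after inoculation differed by design between these stages.

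Of 8 small heat-shock protein genes 6 fell with nuclear GSH in control cultures, and 5 rose and 1 fell in media-change cultures; both list calls were lost (adjusted p = 0.063 and adjusted p = 0.178 with an estimated correlation). The difference between the effects was tested for single genes and not for lists, and that of AT2G29500 was -9.75 ± 0.36. AT1G12010 and the peroxidase AT2G37130 differed the other way, by 7.36 ± 0.26 and 7.29 ± 0.23. Their control effects, 2.41 and 3.04, came from the rise between 102 h and 198 h, and GSHn1 lay close to GSHc1. The control and media-change effects share no array. Among probe sets called in both, 1401 went in the same direction and 3150 in opposite directions. Of the first, 710 were higher in both, where independent lists would share 734.2, and 691 were lower in both, where they would share 628.8. Of the opposite ones, 1548 were higher in control and lower in media-change cultures and 1602 the reverse, where independent lists would share 638 and 723.7. These expected numbers treat all probe sets alike and are too low, because calls lay mostly in brighter probe sets. Of those, 62.9% were called in the control comparison and 52.2% in the media-change one. Of probe sets with a mean under an intensity of 2, 10.2% and 7.2% were called. Across probe sets, which are not independent replicates, the effects correlated at -0.32 (Pearson) and -0.23 (Spearman). Among calls of at least 2-fold, 75 went the same way and 448 opposite ways. The difference between the effects, control minus media-change, passed the threshold for 8727 probe sets, positive in 4140 and negative in 4587.

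At 78 h a nuclear stage (GSHn3, medium changed) and a cytoplasmic stage (GSHc1, control) were available at the same time. Of 9 genes of the replication machinery 7 rose in the nuclear stage and 0 fell, with AT3G42660 higher by 0.96 ± 0.12, POLA3, a primase subunit, by 0.85 ± 0.13 and PRL, a replication licensing protein, by 0.72 ± 0.13. Camera called the list at an adjusted p of 2.83e-07, which held at adjusted p = 0.00886 with an estimated correlation. Ribosome biogenesis genes rose in 8 of 17 cases and fell in 0, AT3G12860 by 0.9 ± 0.16 and AT3G21540 by 0.74 ± 0.15 (adjusted p = 6.01e-09, held at adjusted p = 0.00853 with an estimated correlation). Genes of mitosis and cytokinesis rose in 8 of 20 cases, AT5G45700 by 1.05 ± 0.12 and AT2G28620 by 1.01 ± 0.17 (adjusted p = 4.72e-07, and adjusted p = 0.0989 with an estimated correlation). The preset list of G2 and mitosis was not called: 2 of 6 rose, 2 adjusted over the list alone (camera adjusted p = 0.0682). Among 14 preset lists 2 were called at 78 h, and 0 of these held with an estimated correlation. The 3 list calls that held at 78 h were all of lists added from the annotation. Core histones rose in 2 of 4 cases, 3 adjusted over the list alone, HTB11 by 0.61 ± 0.1 and HTB2 by 0.55 ± 0.12 (adjusted p = 0.00579, and adjusted p = 0.11 with an estimated correlation).

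Of 8 small heat-shock protein genes 6 fell in that nuclear stage, all by at least 2-fold: AT1G53540 was lower by -4.61 ± 0.26 (24.4-fold), AT5G37670 by -4.42 ± 0.42 (21.4-fold) and AT1G52560 by -3.99 ± 0.22. The call (adjusted p = 5.55e-14) held at adjusted p = 0.00886 with an estimated correlation. AT1G54230, AT1G06620 and AT1G10260 were lower by -4.8 ± 0.28, -4.51 ± 0.21 and -4.46 ± 0.31. Higher were AT1G72230 by 2.92 ± 0.21, AT3G15450 by 2.83 ± 0.32, AT3G10080 by 2.46 ± 0.17, MPC by 2.26 ± 0.2 and AT2G37840 by 2.15 ± 0.23. APG8A, an autophagy gene, fell by 1.18 ± 0.18, and the 10 autophagy genes as a list were not called (2 fell, adjusted p = 0.109). In limma 3092 probe sets passed, 1684 higher and 1408 lower, 203 and 367 of them by at least 2-fold, and arrays did not overlap in 33.5% of probe sets against 10% by chance. With array weights 4736 passed. The change of medium goes with the group here.

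From 6 h (nuclear) to 78 h (cytoplasmic) in control cultures, hypoxia and photosynthesis genes rose and ribosome biogenesis genes fell. Both of the hypoxia genes that passed rose by at least 2-fold, AT3G10040, a hypoxia-response transcription factor, by 2.74 ± 0.18 and PDC2, a pyruvate decarboxylase of ethanolic fermentation, by 1.51 ± 0.12, 2 of 3 measured and 2 adjusted over the list alone (adjusted p = 0.00278, held at adjusted p = 0.0488 with an estimated correlation). RCA rose by 2.93 ± 0.16, LHCB4.1 by 2.28 ± 0.12 and PRK by 1.71 ± 0.19, all 3 photosynthesis genes measured and 3 adjusted over the list alone (adjusted p = 0.00015, held at adjusted p = 0.0488 with an estimated correlation). All 17 ribosome biogenesis genes fell, 12 by at least 2-fold, AT5G66540 by 1.95 ± 0.16 and AT3G12860 by 1.82 ± 0.16 (adjusted p = 4.52e-14, held at adjusted p = 0.000901 with an estimated correlation). Core histones fell in 4 of 4 cases, 4 adjusted over the list alone, HTB1 by 1.08 ± 0.12 (adjusted p = 0.00201, held at adjusted p = 0.0488 with an estimated correlation).

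Genes of mitosis rose in the same interval: AUR1 by 1.7 ± 0.12, AUR2 by 1.4 ± 0.12 and BUBR1 by 1.56 ± 0.14. In all, 5 of 6 G2 and mitosis genes were higher and HTR12 lower, the same counts adjusted over the list alone (camera adjusted p = 0.00278, and adjusted p = 0.0915 with an estimated correlation). Autophagy genes rose in 5 of 10 cases, ATG8F by 1.68 ± 0.12 and APG8A by 1.53 ± 0.18 (adjusted p = 0.00289, held at adjusted p = 0.0477 with an estimated correlation). Of 12 glutaredoxins, thioredoxins and peroxiredoxins 5 rose and 0 fell, 5 adjusted over the list alone, PRXIIF by 1.27 ± 0.1 and AT1G77370 by 1.22 ± 0.12 (adjusted p = 0.0187, and adjusted p = 0.0504 with an estimated correlation). Small heat-shock protein genes rose in 6 of 8 cases, AT2G29500 by 4.32 ± 0.29 (adjusted p = 5.6e-06, and adjusted p = 0.0951 with an estimated correlation). Expansins and xyloglucan endotransglucosylases fell in 7 of 14 cases and rose in 0, 7 adjusted over the list alone, XTH18 by 2.19 ± 0.19 (adjusted p = 0.00201, held at adjusted p = 0.0488 with an estimated correlation). The largest rises were those of AT3G29970 (6.14 ± 0.19, 70.3-fold), AT4G39675 (5.97 ± 0.26), AT2G17850 (5.87 ± 0.2), AT5G66985 (5.78 ± 0.23) and AT4G10270 (5.56 ± 0.17). The largest falls were those of AT2G41730 at -5.55 ± 0.23 (from 443 to 9.44), AT2G39210 at -5.53 ± 0.19, AT2G32020 at -4.48 ± 0.22, AT5G66650 at -4.45 ± 0.2 and AT2G38870 at -4.13 ± 0.26. In limma 7779 probe sets passed, 3903 higher and 3876 lower, and 1290 and 1044 by at least 2-fold. After median centring 3631 were higher and 4249 lower.

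From 78 h to 102 h, both cytoplasmic, the ribosomal genes fell and autophagy genes rose. Of 94 cytosolic ribosomal protein genes 73 fell and 0 rose, AT4G30800 by 1.74 ± 0.14, AT4G15000 by 1.1 ± 0.13 and AT3G06700 by 1.08 ± 0.14, and 15 of 17 ribosome biogenesis genes fell, NRPA1 by 1.26 ± 0.14. Both calls (adjusted p = 3.04e-38 and 5.39e-16) held at adjusted p = 0.0019 and 0.000532 with an estimated correlation. Autophagy genes rose in 5 of 10 cases, ATG8F by 1.31 ± 0.12 and ATG8E by 1.12 ± 0.19 (adjusted p = 9.62e-05, held at adjusted p = 0.00547 with an estimated correlation). HTB1 fell by 1.04 ± 0.12 and HTB11 by 0.83 ± 0.1, 2 of 4 core histones and 2 adjusted over the list alone (adjusted p = 0.00306, and adjusted p = 0.0659 with an estimated correlation), and 2 of 3 hypoxia genes fell, 2 adjusted over the list alone, AT3G10040 by 1.38 ± 0.18 (adjusted p = 0.00865, and adjusted p = 0.0528 with an estimated correlation). Glutaredoxins, thioredoxins and peroxiredoxins fell in 3 of 12 cases and rose in 0, with 5 lower and 1 higher adjusted over the list alone; AT3G11630 fell by 0.55 ± 0.11 (adjusted p = 0.0359, and adjusted p = 0.0659 with an estimated correlation). GAT1_2.1, AT5G20790, the peroxidase AT1G71695, AT5G17340 and AT5G04080 rose most, by 4.06 ± 0.21, 4.04 ± 0.29, 3.96 ± 0.29, 3.6 ± 0.23 and 3.36 ± 0.19. AT5G10040, AT1G23100, AT1G61660, AT3G02910 and WRKY22 fell most, by 2.42 ± 0.3, 2.19 ± 0.17, 1.9 ± 0.2, 1.88 ± 0.22 and 1.87 ± 0.15. In limma 3642 probe sets passed, 1592 higher and 2050 lower, and 272 and 194 by at least 2-fold. After median centring 1908 were higher and 1735 lower.

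From 102 h (cytoplasmic) to 198 h (nuclear) small heat-shock protein genes fell to the lowest levels of the control course. Of 8 genes 6 fell and 1 rose. AT2G29500 changed by -8.19 ± 0.29 (from 391 to 1.34), AT1G53540 by -8.1 ± 0.26 (from 324 to 1.18) and AT1G54050 by -6.64 ± 0.2 (list camera adjusted p = 5.94e-08, held at adjusted p = 0.0307 with an estimated correlation). The levels of 1.34 and 1.18 are under an intensity of 2 and had no detection call, so the size of these falls is uncertain. AT5G48570 and AT1G56300, outside that list, changed by -7.26 ± 0.16 and -5.59 ± 0.18. Ribosomal protein genes fell in 87 of 94 cases, AT1G15930 by 1.6 ± 0.09 (adjusted p = 3.74e-30, held at adjusted p = 0.0105 with an estimated correlation). Beta-glucosidases rose in 7 of 20 cases, BGLU28 by 4.98 ± 0.25 and BGLU46 by 3.56 ± 0.32 (adjusted p = 0.000617, held at adjusted p = 0.0248 with an estimated correlation), and mitochondrion-encoded genes in 11 of 15, nad9 by 2.19 ± 0.17 (adjusted p = 8.53e-06, held at adjusted p = 0.02 with an estimated correlation). Sulfate assimilation genes rose in 3 of 4 cases, 3 adjusted over the list alone, SIR, sulfite reductase, by 1.23 ± 0.11 and APS4 by 1.0 ± 0.12 (adjusted p = 0.0044, and adjusted p = 0.163 with an estimated correlation). All 4 core histones rose, 4 adjusted over the list alone, HTB1 by 1.38 ± 0.12 (adjusted p = 0.000508, and adjusted p = 0.0905 with an estimated correlation). The peroxidases AT2G37130 and AT5G64120, AT1G12010 and HIS1-3, a linker histone, rose by 6.23 ± 0.19, 5.04 ± 0.2, 4.96 ± 0.21 and 4.61 ± 0.16. In limma 7536 probe sets passed, 3765 higher and 3771 lower, and 1287 and 953 by at least 2-fold. After median centring 3452 were higher and 4315 lower.

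**Figure D3:**
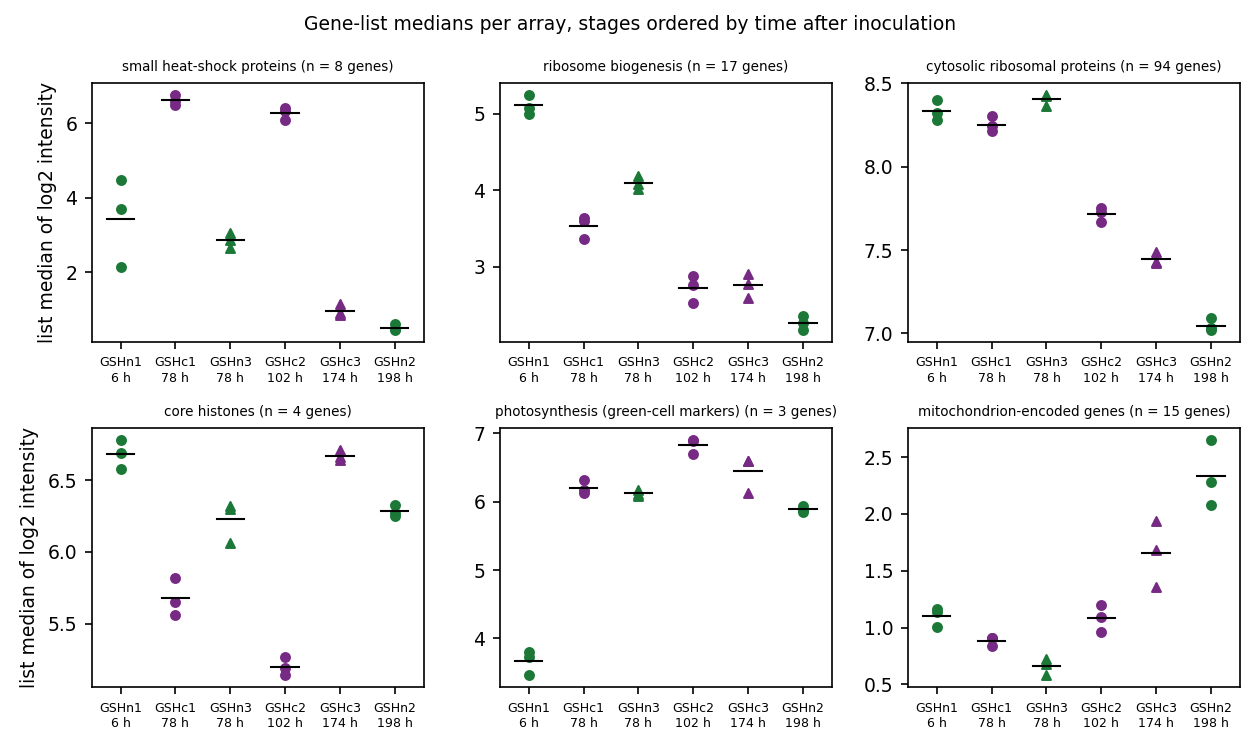
Median log2 intensity of 6 gene lists in each array (vertical axis), with stages ordered by time after inoculation (horizontal axis). Points are arrays, green for nuclear and purple for cytoplasmic GSH, triangles for changed medium, and bars are means of 3 arrays; small heat-shock protein medians were 6.61 at GSHc1 and 6.27 at GSHc2, against 0.51 at GSHn2.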

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

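The tests of opposite localization effects and of heat-shock genes below were chosen after the results were seen; the tests over other splits were set before any split was run, when the real counts were known. The first results differ between control and media-change cultures by a test of the difference itself: 8727 probe sets passed. The genes with the largest differences (control effect minus media-change effect, log2) were AT1G12010 at 7.36, AT2G37130 at 7.29, AT2G30930 at 7.19, AT5G40450 at 6.83 and AT1G05340 at 6.67. In the other direction stood AT2G29500 at -9.75, AT2G17850 at -9.56, AT1G53540 at -9.16, AT5G66985 at -8.59 and AT4G39675 at -8.39. In AT2G29500 the nuclear stages were lower by -6.26 in control cultures and higher by 3.49 after media change.

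The control and media-change effects of localization went opposite ways in 3150 probe sets and the same way in 1401. A mislabelled array is argued against by the closest neighbours: 18 of 18 arrays had their closest array in their own stage, though whole stages exchanged would not show in this. The authors' normalization as a whole cannot be told apart, because a further quantile normalization (2.24 times as many opposite calls) moved the control differences by a median of only 0.006, but a normalization that keeps the order within an array is argued against by 2.46 times as many opposite calls on ranks within arrays. Culture age is a candidate explanation: GSHn3 minus GSHc3 correlated at 0.73 across probe sets with GSHc1 minus GSHn2, which likewise sets a younger stage against an older one but has the localizations turned round. GSH localization, medium and age are not crossed in this design, so an effect of localization beside that of age stays open and untested.

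Small heat-shock protein genes were higher at 78 h and 102 h in control cultures than at the other stages. The authors' normalization as a whole cannot be told apart here either, since the further quantile normalization, with a list median of -3.96 in the control comparison, moved too little to decide, but a normalization that keeps the order within an array is argued against by a list median of -35.6 percentile points on ranks. A single replicate is argued against as well, since the median was at most -3.88 whichever array was left out. Probe sets marked for shared sequence are argued against too, as 0 of the 8 members lie on such a probe set, while cross-hybridization without such a mark was not tested. GSH localization alone is argued against, as the median over the members of GSHc3 minus GSHc1, both cytoplasmic, was -5.61 in a test written after the stage values were seen; localization together with medium or culture age stays open and untested.

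For the comparison of all stages, 3 of 100 splits of the 18 arrays into 9 and 9 called as many probe sets in a fit with 2 groups as the real split, which called 1068; the highest other called 4610. Such splits part replicates of a stage, so a low share excludes only a chance drawing of single arrays and not of stages, and a split that calls several times as many points to the structure of the stages. Regrouping whole stages, 6 of 10 groupings called as many as the real 7549, with 9585 as the highest other. These groupings are too few for a share under 0.05. In the control cultures 1 of 100 splits of the 12 arrays, the real one, called as many as 4015, with 0 as the highest other, and the same limit holds for them; of the 3 groupings of whole control stages 1 called as many as 8729, with 8617 as the highest other, too few to judge. For the difference between effects, 2 of 6 reassignments called as many as 8727, with 9333 as the highest other, again too few to judge.

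The comparisons of 3 arrays with 3 have 10 splits each, too few for a share under 0.05. The real split, 1 in each, called 6873 for media change, 4528 at 78 h, 7806 from 6 h to 78 h, 3389 from 78 h to 102 h and 7184 from 102 h to 198 h, and the highest other called 0 in each. For the differences among stages 1 of 100 splits, the real one, called as many: 11294 among the nuclear stages, with 5398 as the highest other, and 7532 among the cytoplasmic stages, with 3519 as the highest other. These splits also part replicates of a stage. They therefore exclude only a chance drawing of single arrays and not chance differences between stages.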

How the results depend on the processing

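Of 378 values of the main results under 40 alternatives, 350 lay within 1.5 times the reported value and 28 did not. The 350 include all values from fits that left out 1 array, which share nearly all arrays with the main fit. The values with the stage as the unit and with an estimated correlation were among the 28. The filter at log2 2, the added lists and the scaling and omission settings for lists and overlap were chosen after the data were seen. With the replicate block the counts moved little (7522 for all stages, 8688 in control cultures). The numbers show no pairing of the arrays once the stage mean was subtracted from each array. Between stages, 1 of 45 same-numbered pairs then correlated over 0.1, as did 2 of 90 pairs with different numbers. Of 18 arrays 7 correlated best with an array of their own number in another stage. The filter at log2 6 left fewer probe sets. It called 1544 for all stages, 1673 in control cultures, 1688 for media change, 1783 for the difference of effects and 888 at 78 h. Along the time course it called 1574, 1259 and 1685, with 2009 among nuclear and 1890 among cytoplasmic stages. Of 80 named genes, counted once per comparison, 50 stayed past the threshold and the others were removed by the filter. It gave 6 list calls, 5 of them among the 29. Calls of at least 2-fold numbered 625, 1580, 1797, 3814, 570, 2334, 466 and 2240 in the order of the comparisons above, and the overlap 75 in the same and 448 in opposite directions. With the stage as the unit the comparison of all stages called 0. There 787 probe sets (3.5%) had an unadjusted p under 0.05 in limma, a share below that expected by chance. With a random block 7 were called (10.6% at an unadjusted p under 0.05), or 1805 in control cultures. The fit on stage means tests fewer units. The random-block fits share a correlation over all probe sets and still count single arrays, so they do not make the stage the unit. Array weights gave 4736 at 78 h; the cause was not tested. Of 29 list calls 4 held with an estimated correlation, and the added lists gave 55. Median centring and quantile normalization turned the direction of 0 called lists. This says little, since camera compares members with all other genes, which centring shifts alike. Quantile normalization moved the control differences by a median of only 0.006.

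Leaving out each array gave 7101 to 7491 for all stages, 8218 to 8960 in control cultures, 6173 to 7295 for media change, 8027 to 8832 for the difference, 2223 to 3340 at 78 h, 6932 to 7982, 2673 to 3904 and 6788 to 7754 along the time course, and 27 to 31 list calls. Leaving out stage GSHn1 turned the all-stage difference of ATG8F to 0.1. Leaving out GSHn2 turned AT4G39200 to 0.11, AT5G35530 to 0.09, BGLU46 to -0.1, scpl50 to -0.3, SWEET10 to -0.05, RALFL33 to -0.13, SEC10 to -0.08 and cox1 to -0.11. Leaving out GSHn3 turned NRT2.5 to -0.24; the cause was not tested. Dim probe sets limit the calls: of 10586 with a mean under an intensity of 2, 7.5% were called between all stages, against 55.5% of 12160 brighter ones.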

Other observations

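Further lists and single genes differed between stages of the control cultures; both from 6 h to 78 h and from 102 h to 198 h localization changed with age. Of 55 class III peroxidases 15 rose and 3 fell from 102 h to 198 h (adjusted p = 0.00101, and adjusted p = 0.128 with an estimated correlation), AT5G17820 by 3.94 ± 0.15. SWEET10, a sugar transporter, rose by 3.58 ± 0.15 in the same interval, and GH9B8 and GH9C2, endoglucanases, fell by 3.8 ± 0.16 and 2.71 ± 0.17; their list was not called (adjusted p = 0.0962). Vacuolar sorting genes rose in 6 of 12 cases, VPS24.1 by 1.16 ± 0.12 (adjusted p = 0.00265, held at adjusted p = 0.0248 with an estimated correlation). Between 6 h and 78 h SCPL45, a carboxypeptidase-like gene, rose by 2.29 ± 0.14 and UGT73B4, a glycosyltransferase, fell by 2.49 ± 0.15.

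The array medians of the small heat-shock protein list spread more at 6 h (SD 1.19, n = 3) than at GSHc1 (SD 0.14) or GSHn2 (SD 0.09). Plastid-encoded genes went both ways from 102 h to 198 h: 25 of 69 rose and 15 fell, with rpl20 higher by 2.98 ± 0.24 and psaB lower by -1.47 ± 0.21 (adjusted p = 0.0463, and adjusted p = 0.524 with an estimated correlation).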
